A study of Mus musculus with 69 samples.

How the data were processed

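RNA and chromatin were measured in the nucleus accumbens of male mice that were reared under standard conditions or exposed to early life stress (ELS). RNA was sequenced from 32 libraries in 4 groups of 8. Standard GFP and ELS GFP animals carried a control vector, Standard Dot1l overexpression animals a vector meant to raise Dot1l, and ELS Dot1l knockdown animals a vector meant to lower it. Chromatin immunoprecipitation (ChIP) for H3K79me2 was labelled in 9 Standard and 9 ELS libraries, beside 9 Standard and 10 ELS input libraries. Groups were taken from the labels. Replicate numbers of RNA libraries follow the order of the sample titles within a group and pair nothing between groups.

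Per the labels' protocols, RNA was extracted from tissue with a column kit, reverse transcribed and sequenced in pairs. The deposited RNA table holds raw counts per Ensembl mouse gene, which the authors had not normalized: its values are whole numbers with a different total in each library. Per the submitters' processing notes, the tools were FastQC, HISAT2, featureCounts and DESeq2 and the build was mm10. The notes give neither their versions nor their roles, and the name of the deposited table speaks of HTSeq, so which tool and which rule for overlapping genes made the counts stays open. Whether strand was used in counting is not given in the sources used here, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Symbols were matched for 52403 of the 52636 gene IDs. All 32 columns matched the title of an RNA library, and 0 columns were left unmatched.

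The authors deposited 1 H3K79me2 peak list per rearing group, each peak with a fold enrichment (a ratio) and a q-value per the file headers. The peak caller, the background of the fold and how the libraries were combined are not given in the sources used here. Folds rank peaks within a list, 1 alternative filters both lists at their common median of 1.94, and medians of the lists are given as the authors' values. The q-values lie at or below 0.0497 in the Standard list and 0.0489 in the ELS list. A peak stands on several annotation lines when it lies near several genes, so the 475994 Standard and 432179 ELS lines were reduced to 117819 and 106374 distinct peaks. Coordinates are those of the lists, on mm10. Peaks called per library, and counts per ChIP or input library, were not analysed here.

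Counts were tested with edgeR 4.0.16 (R 4.3.3): TMM factors, filterByExpr, which left 14016 genes, and the quasi-likelihood test with robust dispersion in 1 fit of the 32 libraries with a mean per group and 28 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. The SE of a log2 fold change was derived from the test, as its absolute value over the square root of the quasi-likelihood F. It is not a measured spread over libraries. Levels in CPM (counts of a gene per 1 M counts) use the TMM library sizes, and values per group are means ± SD over 8 libraries. The common biological coefficient of variation was 0.566. The main contrasts were ELS GFP minus Standard GFP, Standard Dot1l overexpression minus Standard GFP, and ELS Dot1l knockdown minus ELS GFP. Secondary contrasts set the knockdown group against Standard GFP and the overexpression group against ELS GFP.

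Before the data were examined, 34 gene lists for cell types, synapses, stress and chromatin were fixed. They were tested with camera (limma 3.58.1, voom, inter-gene correlation 0.01, 2-sided, adjusted over the 34 lists), again with an estimated correlation, and with fry. A rule fixed at the same time chose the genes named in the text. It takes up to 10 genes per direction past the threshold, or the 6 with the smallest p where fewer pass, and up to 3 per direction in the secondary contrasts. It adds Dot1l, Kdm2b, striatal markers, immediate early genes, Bdnf, Fkbp5 and Crh in every contrast, and up to 4 members of each list past its threshold. For peaks it takes the 5 with the highest fold in each list that overlap no peak of the other list, and those at the genes always named. Some genes and peaks that the rule picks are not reported here. Genes named outside this rule are marked as chosen after their values were seen.

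Effects of the main contrasts were correlated across genes as differences in mean log2 CPM (prior count 2). ELS and overexpression share the Standard GFP libraries, and ELS and knockdown share the ELS GFP libraries. Shared libraries move a correlation away from 0 with no effect at all, so the shared group was also split at random into groups of 4 in 100 draws, and 100 regroupings of the libraries gave the value with no effect. Peak lists were compared with bedtools 2.31.1 at an overlap of at least 1 bp. Peaks were joined to genes by the names in the lists, and the lengths covered were summed per gene. These are full peak widths, not clipped to the gene. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

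Depth ran from 0.314 to 11.1 M (mega) counts per RNA library. The edgeR step was tested on simulated counts with the real means and depths, in which 200 genes were changed. For the ELS contrast, on 13681 simulated genes, it called 13 of 98 genes changed 2-fold and 69 of 98 changed 4-fold. For overexpression, on 13707 genes, it called 14 of 97 and 70 of 95. For knockdown, on 13740 genes, it called 18 of 96 and 60 of 99. For knockdown against Standard GFP it called 17 of 99 and 62 of 97, and for overexpression against ELS GFP 17 of 98 and 69 of 93. Simulated raised and lowered lists were recovered by camera in all of these runs. Over all 5 contrasts 18 of 427 calls were false (4.2%). Each simulated gene was drawn independently of the others. The simulation therefore gives no rate of false calls for genes or lists that vary together between libraries. Counting intervals in the text are 95% Wilson binomial intervals and cover counting error only.

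Alternatives fixed before the data were examined were DESeq2 size factors in the edgeR fit, no filter on low counts, a stricter filter, DESeq2 1.42.0, limma voom with quality weights, only the 2 groups compared, the number or the letter of the sample title as a factor, surrogate variables (sva 3.50.0), an adjusted p under 0.10, an estimated correlation, fry, other prior counts, rank correlation, and stricter or merged peaks. Chosen after seeing the data were fits without the 4 libraries under 1 M (mega) counts, without the 10 most abundant genes, without the library of each group that dominates most genes, and without Standard GFP replicate 6, and list tests with quality weights. A library was said to dominate a gene when it held over 50% of its group's summed CPM.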

Results

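The series asks how early life stress (ELS) acts on methylation of histone H3 at lysine 79 (H3K79me), the mark laid down by the methyltransferase DOT1L, in medium spiny neurons of the nucleus accumbens, and on the genes downstream of it. The data are RNA counts for 14016 genes in 32 libraries, 8 per group, and a list of H3K79me2 peaks for each rearing group. Libraries held 0.314 to 9.8 M counts (mega, 1e6) in Standard GFP, 1.76 to 11.1 M in ELS GFP, 2.48 to 7.88 M in Standard Dot1l overexpression and 0.462 to 8.8 M in ELS Dot1l knockdown. The libraries under 1 M counts were Standard GFP replicates 1, 4 and 5 (0.98, 0.314 and 0.546 M) and ELS Dot1l knockdown replicate 7 (0.462 M).

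The tissue's own neurons were clearly present. Pde10a, the phosphodiesterase of medium spiny neurons, averaged 547 ± 248 CPM in Standard GFP (SD, n = 8), Penk (enkephalin, typical of D2-type neurons) 203 ± 150 CPM and Drd2 (dopamine receptor D2) 108 ± 70.7 CPM. Drd1 (dopamine receptor D1) averaged 10.9 ± 10.3 CPM and Tac1 (substance P, typical of D1-type neurons) 6.55 ± 8.6 CPM. A few features took a large part of the counts in every group. Cdk8 held a mean of 14.99% of a library's counts, CT010467.1 held 12.6%, Jarid2 5.4% and Lars2 5.01%, features chosen here after their values were seen. The 10 most abundant features, which include the mitochondrial ribosomal RNAs mt-Rnr2 and mt-Rnr1, took from 36.1% to 59.5% of a library's counts. Whether the reads at Cdk8, Jarid2 or Lars2 come from their mRNA was not tested.

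Dot1l, the target of both vectors, did not differ between groups past the threshold. It averaged 33.9 ± 10.8 CPM in Standard GFP, 35.6 ± 11.4 CPM in ELS GFP, 43.1 ± 19 CPM in the libraries labelled overexpression and 43.1 ± 15.2 CPM in those labelled knockdown (SD, n = 8 each). Its log2 fold change was 0.33 (SE 0.27, adjusted p = 0.741) for overexpression against Standard GFP. For the libraries labelled knockdown against ELS GFP it was 0.28 (SE 0.27, adjusted p = 0.985), on the side opposite to the label, and 5 of the 8 lay above the ELS GFP median. ELS and Standard GFP differed by 0.05 (SE 0.27, adjusted p = 0.974). Per the labels' protocol the RNA came from whole tissue, in which a change within a small part of the cells can be diluted. Whether the knockdown labels are right is not settled by these values, and the groups below are named by their labels.

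**Figure D1:**
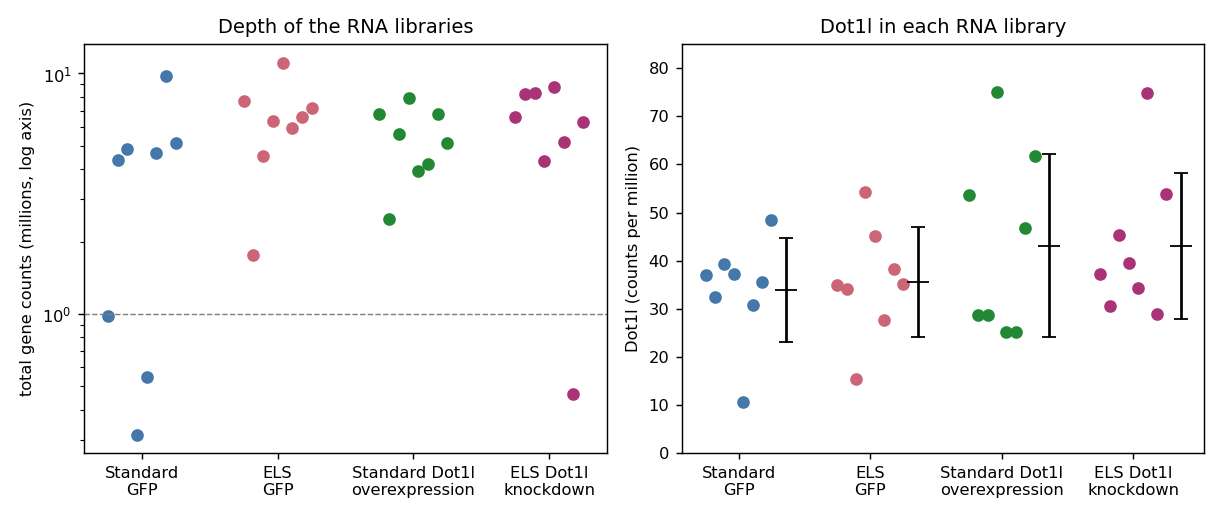
The left panel plots total gene counts in M on a log axis for each RNA library by group, with a dashed line at 1 M. The right panel plots Dot1l in CPM for the same libraries, with black bars for the mean and SD (n = 8): the means lie at 33.9, 35.6, 43.1 and 43.1 CPM and the groups overlap.

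The ELS comparison asks what ELS changes in the accumbens of animals with the control vector. Astrocyte, myelin and shared medium spiny neuron markers were lower in ELS GFP than in Standard GFP as sets. Microglia, oligodendrocyte precursor and interneuron markers did not pass. Of 12 microglia markers, however, 10 were lower and 2 higher, at a median log2 fold change of -0.48 (camera adjusted p = 0.457). That median lies close to the myelin median, so the test does not show microglia markers to be unchanged. All 10 tested astrocyte markers were lower, with a median log2 fold change of -0.57 (camera adjusted p = 4.17e-06; adjusted p = 0.107 with an estimated correlation). Of 14 oligodendrocyte and myelin genes 13 were lower, at a median of -0.49 (adjusted p = 4.17e-06; adjusted p = 0.252 with an estimated correlation). Of 15 markers shared by medium spiny neurons 13 were lower, at a median of -0.56 (adjusted p = 0.0199; adjusted p = 0.863 with an estimated correlation). Cytosolic ribosomal protein genes were higher as a set, 44 of 70 at a median of only 0.07 (adjusted p = 0.000115; adjusted p = 0.805 with an estimated correlation). The astrocyte median was -0.37 without Standard GFP replicate 6, -0.37 without the dominating libraries and -0.325 with surrogate variables, and the shared neuronal median -0.28 with surrogate variables. The ribosomal median was 0.04 without the dominating and 0.175 without the shallow libraries.

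Among the astrocyte genes, Gja1 (connexin 43) averaged 63.4 ± 31.2 CPM in Standard GFP and 34.6 ± 10.3 CPM in ELS GFP (SD, n = 8), a log2 fold change of -0.88 (SE 0.26, adjusted p = 0.135), and all 8 ELS libraries lay below the Standard median. Slc1a3, a glutamate transporter, had -0.64 (SE 0.24), the water channel Aqp4 -0.67 (SE 0.25) and Fgfr3 -0.71 (SE 0.29). Among the myelin genes, Myrf, their regulator, had -0.84 (SE 0.34). Mag had -0.60 (SE 0.30) and Cldn11 -0.64 (SE 0.33). Of the neuronal markers, Pde10a had -0.63 (SE 0.29), Gng7 -0.63 (SE 0.33) and Pde1b -0.72 (SE 0.38). None of these genes passed over all genes tested. Adjusted over the list alone, 3 astrocyte markers passed, 0 myelin genes and 0 shared neuronal markers. The ribosomal list held members on both sides: Rpl7a had 0.96 (SE 0.35) and Rpl10a 0.80 (SE 0.30), while Rpl18 had -1.82 (SE 0.50) and Rpl22 -0.99 (SE 0.40). Standard GFP replicate 1 held 44.4% of Rpl18 and 40.1% of Rpl22 in its group, the log2 ratios of medians were -0.13 and 0.10, and Rpl22 turned to 0.26 without the shallow libraries.

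Genes that separate D1-type from D2-type neurons did not pass singly or as lists. Penk averaged 203 ± 150 CPM in Standard GFP and 73.2 ± 76.9 CPM in ELS GFP (log2 -1.49, SE 0.54, adjusted p = 0.218), below the Standard median in 7 of 8 ELS libraries. Adora2a, the adenosine receptor of D2-type neurons, had -1.53 (SE 0.61, adjusted p = 0.282), Drd1 -1.67 (SE 0.71, adjusted p = 0.319) and Drd2 0.22 (SE 0.59). ELS GFP replicate 2 held 61.7% of Drd2, whose log2 ratio of medians was -0.56 and which turned to -0.83 without the dominating libraries. Tac1 had -0.91 (SE 0.63), with 46.2% of its Standard GFP level in replicate 8 and a log2 ratio of medians of 0.74 on the other side. Pdyn had -0.83 (SE 0.61) and Ppp1r1b (DARPP-32) -0.87 (SE 0.50). The D2-type list (adjusted p = 0.457) and the D1-type list (adjusted p = 0.457) did not pass. Activity and stress genes showed no difference past the threshold: Fos had -0.05 (SE 0.48), Fosb -1.05 (SE 0.59), Egr1 -0.04 (SE 0.34), Bdnf -0.14 (SE 0.52), Fkbp5 -0.18 (SE 0.41) and Kdm2b, an H3K79 demethylase candidate and Polycomb protein, -0.08 (SE 0.30). Crh had too few counts to be tested.

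Gene by gene with edgeR, 0 genes passed an adjusted p of 0.05 for ELS, against 1644 at an unadjusted p under 0.05, where other splits of the same libraries gave a median of 1521. Of these, 560 were higher and 1084 lower in ELS. DESeq2 called 85 genes and limma voom with quality weights called 0. The lower genes with the smallest p were Pdik1l (-3.21, SE 0.68), Nifk (-2.95, SE 0.63), Rfc5 (-3.26, SE 0.70), Ptrhd1 (-4.83, SE 1.05), Zfp949 (-2.83, SE 0.63) and Gm9774 (-3.66, SE 0.82). The higher ones were Stpg4 (4.47, SE 0.99), Timm17a (2.70, SE 0.63), Heyl (4.94, SE 1.17), Dusp5 (2.62, SE 0.63), Acsl5 (2.32, SE 0.56) and Gm47962 (4.06, SE 0.99). All 12 had an adjusted p of 0.12. In 11 of the 12, 1 library held over 50% of the higher group's CPM: Heyl reached 121 CPM in ELS GFP replicate 2 and a median of 0.777 CPM over its group. The same library held 405 CPM of Timm17a, and Standard GFP replicate 6 held 223 CPM of Rfc5.

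The overexpression comparison asks what the Dot1l overexpression vector does in standard-reared animals, set against Standard GFP. Synaptic and myelin genes were lower as sets and ribosomal and mitochondrial transcripts higher. All 14 myelin genes were lower at a median log2 of -0.37 (camera adjusted p = 5.48e-06; adjusted p = 0.202 with an estimated correlation). Of 70 ribosomal protein genes 54 were higher at a median of 0.24 (adjusted p = 1e-09; adjusted p = 0.202 with an estimated correlation), and all 13 mitochondrially encoded mRNAs were higher at 0.20 (adjusted p = 0.00488; adjusted p = 0.578 with an estimated correlation). The mitochondrial call was lost without the dominating libraries (median 0.05, adjusted p = 0.314) and with quality weights (adjusted p = 0.0816). With surrogate variables the mitochondrial median was 0.015 and the ribosomal 0.155. In all, 14 of the 34 lists passed, 3 higher and 11 lower, and 0 passed with an estimated correlation or with fry.

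Lists of synaptic genes were called lower, in part through Standard GFP replicate 6. Of 21 glutamate receptor genes 18 were lower (median -0.19, adjusted p = 0.0016; adjusted p = 0.371 with an estimated correlation), with Grin3a at -1.05 (SE 0.43) and Grik2 at -0.37 (SE 0.18). Of 20 postsynaptic scaffold genes 18 were lower (median -0.20, adjusted p = 0.00349; adjusted p = 0.459 with an estimated correlation), with Dlg1 at -0.77 (SE 0.26), Homer1 at -0.72 (SE 0.29), Dlgap4 at -0.32 (SE 0.20) and Nlgn2 at -0.48 (SE 0.31). Without replicate 6, a fit chosen after seeing the data, this list was lost (median 0.00, adjusted p = 0.258), and Dlgap4 (0.02) and Nlgn2 (0.05) turned. Of 19 genes for GABA synthesis, transport and receptors 14 were lower (median -0.22, adjusted p = 0.00491; adjusted p = 0.202 with an estimated correlation). Gabra4, a GABA receptor subunit, averaged 75.2 ± 43.1 CPM in Standard GFP and 43.1 ± 7.12 CPM with overexpression (SD, n = 8), a log2 fold change of -0.81 (SE 0.22, adjusted p = 0.145), and all 8 overexpression libraries lay below the Standard median. Gabra2 had -0.82 (SE 0.26), and these 2 genes passed when adjusted over the list alone. Slc32a1, the vesicular GABA transporter, had -1.33 (SE 0.52), with 52.9% of its Standard GFP level in replicate 6. Without that library the GABA list had a median of -0.03 (adjusted p = 0.0316) and the glutamate list -0.07 (adjusted p = 0.0263). Of 22 presynaptic release genes 13 were lower (median -0.05, adjusted p = 0.0127; adjusted p = 0.578 with an estimated correlation), with Syn3 at -0.79 (SE 0.22), Vamp1 at -1.39 (SE 0.54), Pclo at -0.50 (SE 0.23) and Syt1 at -0.38 (SE 0.19). It too was lost without replicate 6 (median 0.07, adjusted p = 0.258), which held 54.3% of Vamp1. Of 30 potassium channel genes 20 were lower (median -0.15, adjusted p = 0.0195; adjusted p = 0.49 with an estimated correlation), with Kcnj2 at -1.32 (SE 0.57), Kcnj9 at -0.68 (SE 0.34), Kcnj4 at -0.50 (SE 0.26) and Kcnj3 at 0.61 (SE 0.31), which turned to -0.02 without the dominating libraries. The potassium channel median was -0.055 without replicate 6 (adjusted p = 0.0331), and the call was lost without the shallow libraries (adjusted p = 0.0781) and with quality weights (adjusted p = 0.0554). Quality weights also ended the postsynaptic (adjusted p = 0.0779) and presynaptic calls (adjusted p = 0.254). Without the dominating libraries, a fit that keeps replicate 6, medians were further from 0, at -0.30 for glutamate receptor, -0.34 for postsynaptic, -0.25 for presynaptic and -0.26 for potassium channel genes. With surrogate variables the postsynaptic median was -0.13 and the presynaptic -0.08, and without the shallow libraries the presynaptic was -0.085.

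Neuropeptide and stress signalling genes were lower as a set in the overexpression group, 10 of 14 at a median of -0.42 (adjusted p = 0.00514; adjusted p = 0.0563 with an estimated correlation). Penk had -1.14 (SE 0.54), Crhr1 (a receptor of corticotropin-releasing hormone) -1.43 (SE 0.59), Oprd1 (delta opioid receptor) -0.86 (SE 0.46) and Tac1 -1.11 (SE 0.63). Crhr1 had 71.7% of its Standard GFP level in replicate 6 and 0.37 without that library, and medians of Crhr1 and Tac1 were higher with overexpression (log2 0.44 each). The list's median was -0.21 without replicate 6 (adjusted p = 0.0263), -0.18 without the shallow libraries and -0.23 with surrogate variables. The other lower lists were shared medium spiny neuron markers, 12 of 15 at -0.19 (adjusted p = 0.011; adjusted p = 0.578 with an estimated correlation), oligodendrocyte precursor markers, 5 of 7 at -0.24 (adjusted p = 0.0195; adjusted p = 0.371 with an estimated correlation), interferon-stimulated genes, 15 of 23 at -0.20 (adjusted p = 0.0195; adjusted p = 0.67 with an estimated correlation), and axon guidance genes, 23 of 36 at -0.11 (adjusted p = 0.0492; adjusted p = 0.578 with an estimated correlation). The interferon and axon guidance calls were lost with the title number as a factor (adjusted p = 0.0507 each) and with quality weights (adjusted p = 0.0618 and 0.066), and the interferon call without the dominating libraries (median -0.09, adjusted p = 0.0583). The precursor call was lost with quality weights (adjusted p = 0.0618). Without replicate 6 the precursor median was -0.13 and the interferon median -0.12. With surrogate variables the interferon median was -0.075 and the axon guidance median -0.008. Without the dominating libraries the precursor median was -0.38 and the axon guidance median -0.17, and without the shallow ones the interferon median was -0.12 and the shared neuronal median -0.31. Glucocorticoid-induced genes were higher in 10 of 15 at 0.35 (adjusted p = 0.0256; adjusted p = 0.371 with an estimated correlation), with Fkbp5 at 0.74 (SE 0.41), Ddit4 at 1.24 (SE 0.59) and Cdkn1a at 0.87 (SE 0.54), but Plin4 at -2.49 (SE 1.03). Overexpression replicate 4 held 50.5% of Fkbp5, whose log2 ratio of medians was 0.08. Standard GFP replicate 1 held 91.8% of Plin4, which turned to 1.34 without the shallow libraries. The glucocorticoid call was lost with quality weights (adjusted p = 0.172), and with surrogate variables its median was 0.09. Astrocyte markers, at a median of -0.06, did not pass here (adjusted p = 0.529).

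Members with small p in the remaining lists were as follows. Mag had -0.71 (SE 0.30), Aspa -0.77 (SE 0.42) and Myrf -0.60 (SE 0.34). Neu4, of the precursor list, had -3.70 (SE 0.93), with 91% of the Standard GFP CPM in replicate 6, and Cspg4 had -0.94 (SE 0.40). Rpl32 had 1.30 (SE 0.40), Rps12 1.43 (SE 0.46) and Rpl18 -1.28 (SE 0.50), although 1 overexpression library held 55.5% of Rpl32 and the log2 ratio of medians of Rpl18 was 0.26. Of the mitochondrial mRNAs, mt-Co2 had 0.34 (SE 0.19) and mt-Nd3 0.44 (SE 0.28). Usp18, interferon-stimulated, had -0.87 (SE 0.41). Oas1a, of the same list, had -1.81 (SE 0.72), with 84.2% of its Standard GFP level in replicate 6 and 0.66 without that library. Ephb3 had 1.38 (SE 0.55) and Sema6a 0.65 (SE 0.29) in an axon guidance list that was lower on balance, with 57.5% of Ephb3 in overexpression replicate 2 and Sema6a at -0.04 without the dominating libraries. Drd1 (-0.35, SE 0.68), Drd2 (-0.39, SE 0.59), Adora2a (-0.91, SE 0.60), Pdyn (-0.81, SE 0.61), Ppp1r1b (0.17, SE 0.50), Fos (-0.03, SE 0.48), Egr1 (-0.14, SE 0.34), Bdnf (0.18, SE 0.52) and Kdm2b (-0.27, SE 0.30) did not pass.

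With edgeR 0 genes passed for overexpression, against 1524 at an unadjusted p under 0.05 (644 higher, 880 lower). DESeq2 called 41 genes and limma voom with quality weights called 0. Lower genes with the smallest p were Nkd1 (-2.15, SE 0.48), a Wnt antagonist, Tarsl2 (-1.88, SE 0.43), Sec22a (-1.61, SE 0.37), Ppox (-3.02, SE 0.69), an enzyme of haem synthesis, Ddr1 (-1.39, SE 0.32), a collagen receptor, and Tsr3 (-3.36, SE 0.77). All 8 overexpression libraries lay below the Standard GFP median for each of these 6. Nos2, inducible nitric oxide synthase, had 3.04 (SE 0.74) and lay above the Standard median in 6 of 8 libraries. The other 5 higher features were gene models without a common name. All 12 had an adjusted p of 0.137, and in 8 of them 1 library held over 50% of the higher group's CPM. Without the 4 libraries under 1 M counts, a fit chosen after seeing the data, 18 genes passed, all lower, among them Tarsl2 (adjusted p = 0.0366) and Sec22a (adjusted p = 0.0366). The same fit gave 7 genes for ELS, all lower, among them Rfc5 (adjusted p = 0.0482) and Fa2h (adjusted p = 0.0482), a myelin lipid enzyme named here after its value was seen. That fit keeps Standard GFP replicate 6. Over all 8 Standard GFP libraries, replicate 6 held 56.3% of Tarsl2, 47.8% of Sec22a and 85.6% of Rfc5. Over the same libraries their log2 ratios of medians were -0.81, -0.95 and -0.79, against log2 fold changes of -1.88, -1.61 and -3.26.

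The knockdown comparison asks what the knockdown vector does in animals with ELS, set against ELS GFP. Interferon-stimulated genes were higher as a set, 20 of 23 at a median log2 of 0.38 (camera adjusted p = 0.000215; adjusted p = 0.998 with an estimated correlation). The call was lost with the title number as a factor (adjusted p = 0.173), and with surrogate variables the median was 0.02. Usp18 had 0.75 (SE 0.40), Bst2 0.62 (SE 0.35) and Rtp4 0.65 (SE 0.37), while Isg15 had -1.83 (SE 0.65) with 82.2% of its ELS GFP CPM in replicate 2. Ribosomal protein genes were higher in 45 of 70 at 0.12 (adjusted p = 0.0141; adjusted p = 0.998 with an estimated correlation; adjusted p = 0.11 with the title number; adjusted p = 0.0762 with quality weights) and at 0.02 with surrogate variables, with Rpl7 at 0.44 (SE 0.23), Rps25 at 0.52 (SE 0.28), Rpl17 at -0.45 (SE 0.23) and Rpl7a at -0.66 (SE 0.34). All 12 microglia markers were higher at 0.43 without passing (adjusted p = 0.0611; adjusted p = 0.998 with an estimated correlation), and with surrogate variables their median was -0.23. The list passed without the shallow libraries (adjusted p = 0.0271), without the dominating libraries (adjusted p = 0.00195) and with quality weights (adjusted p = 0.000671). It did not pass with the title number (adjusted p = 0.428). It passed without Standard GFP replicate 6 (median 0.43, adjusted p = 0.0411), but that library is in neither group of this contrast and acts only through the shared fit. With an estimated correlation the fits without shallow libraries, dominating libraries and replicate 6 gave adjusted p = 0.954, 0.958 and 0.996.

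Marker sets called lower in ELS did not pass with knockdown, in libraries whose Dot1l level was not lower. Astrocyte markers had a median of 0.09, with 6 of 10 higher (camera adjusted p = 0.847), and myelin genes 0.04, with 9 of 14 higher (adjusted p = 0.847). Shared medium spiny neuron markers had 0.07, with 12 of 15 higher (adjusted p = 0.78). Penk averaged 75.3 ± 52.9 CPM with knockdown and 73.2 ± 76.9 CPM in ELS GFP (log2 0.06, SE 0.53, adjusted p = 0.998). Drd1 had 1.19 (SE 0.70), with 65.1% of its knockdown level in replicate 6, Drd2 -0.59 (SE 0.58), Adora2a -0.20 (SE 0.60), Tac1 0.09 (SE 0.63), Fosb 1.17 (SE 0.57), Fos 0.68 (SE 0.47), Egr1 -0.25 (SE 0.33) and Fkbp5 -0.28 (SE 0.40). The 17 genes of the Dot1l complex and H3K79 regulators had medians of -0.08 for ELS, 0.03 for overexpression and 0.01 for knockdown, and did not pass in any of the 3.

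With edgeR 0 genes passed for knockdown, against 866 at an unadjusted p under 0.05, where other splits of the same libraries gave a median of 839. DESeq2 called 2 genes and limma voom with quality weights called 0. Ankdd1a (2.39, SE 0.60) was above the ELS GFP median in all 8 knockdown libraries, and Stoml3 (-3.00, SE 0.71) below it in all 8. Triqk (-3.07, SE 0.63), Bdh1 (-1.84, SE 0.43), a ketone body enzyme, Rrs1 (-2.96, SE 0.70), Osgepl1 (-4.19, SE 0.94) and Enpp1 (-3.86, SE 0.92) were the other lower genes. Pgam2 (4.55, SE 0.98), Lipc (4.36, SE 0.98), H2afx (4.13, SE 1.04), Elovl2 (2.85, SE 0.76) and Fam189a2 (2.40, SE 0.64) were the other higher ones. Adjusted p-values of the 12 ran from 0.277 to 0.335. In 10 of the 12, 1 library held over 50% of the higher group's CPM, and the log2 ratio of medians of Elovl2, with 84.4% in knockdown replicate 7, was -0.25. The same library held 94% of its group's CPM for Lipc and 96.7% for H2afx.

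**Figure D2:**
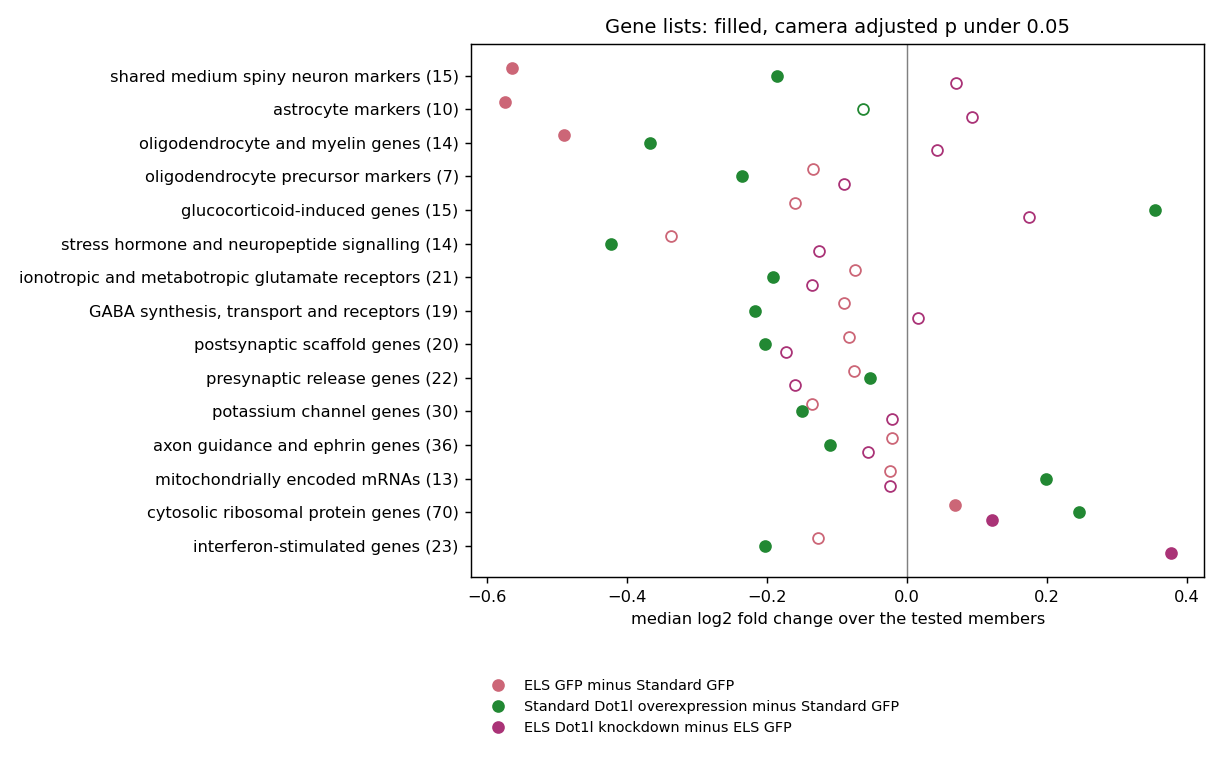
Each point is the median log2 fold change over the tested members of a gene list (their number in brackets) in 1 of the 3 main comparisons, for the lists that passed camera in at least 1 of them. Filled points passed an adjusted p of 0.05: oligodendrocyte and myelin genes lie at -0.49 for ELS and -0.37 for overexpression, and interferon-stimulated genes at 0.38 for knockdown.

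Across groups, the knockdown libraries and Standard GFP differed at 1515 genes at an unadjusted p under 0.05 (436 higher, 1079 lower) and at 0 past the threshold with edgeR. DESeq2 called 74 genes and limma voom with quality weights called 0. Neu4 (-5.13, SE 1.02), Marveld1 (-3.70, SE 0.76) and Ptrhd1 (-4.98, SE 1.07) had the smallest p among the lower genes, each at an adjusted p of 0.0948. Pgam2 (4.56, SE 1.03), Lipc (4.64, SE 1.07) and 1110032A03Rik (1.93, SE 0.45) had it among the higher. In 5 of these 6, all but 1110032A03Rik, 1 library held over 50% of the higher group's CPM, such as Standard GFP replicate 6 with 91% of Neu4. Overexpression against ELS GFP gave 936 genes at an unadjusted p under 0.05 and 0 past the threshold with edgeR, 2 with DESeq2 and 0 with voom. Here Ildr1 (3.66, SE 0.84), Hepacam (1.89, SE 0.46) and Tmem70 (2.99, SE 0.76) were the higher genes with the smallest p, and Dusp5 (-2.58, SE 0.61), Stard4 (-3.78, SE 0.91) and Timm17a (-2.53, SE 0.61) the lower ones, each at an adjusted p of 0.328. In all 6, 1 library held over 50% of the higher group's CPM. ELS GFP replicate 2 held 93.8% of Stard4, whose log2 ratio of medians was 0.07, and 81.7% of Timm17a.

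Whether the overexpression vector moves the same genes as ELS was asked by correlating both effects across 14016 genes, which are not independent replicates. With the shared Standard GFP libraries r was 0.703, where regrouped libraries gave a mean of 0.494 (range 0.253 to 0.715). The covariance was 0.1574 against 0.0985 after regrouping. With the Standard GFP libraries split so that the effects share none, r was 0.055 (SD 0.033 over 100 draws). ELS and knockdown effects had r of -0.458 with the shared ELS GFP libraries, where regrouping gave a mean of -0.471, and -0.081 (SD 0.048) with them split. The covariance was -0.0955 against -0.1004. Overexpression and knockdown, which share no library, had r of -0.068, and regrouped libraries ran from -0.206 to 0.206.

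H3K79me2 lay in the bodies and promoters of genes in both rearing groups. The Standard list held 117819 peaks over 126.1 Mb and the ELS list 106374 peaks over 92.6 Mb, with 97.77% and 98.02% of them in a gene or promoter class. Median widths were 512 and 478 bp, and median folds in the authors' values 1.96 and 1.92. Peaks occurred at 8063 genes in both lists, at 821 in the Standard list only and at 133 in the ELS list only. There is 1 list per group, so no difference between the lists has a replicate check or a p-value.

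The ELS list lay largely inside the Standard list. Of the ELS peaks 90.8% overlapped a Standard peak, and of the Standard peaks 62.6% overlapped an ELS peak. With a reciprocal overlap of 50%, a stricter rule, these shares were 40% and 36.1%. The 44050 Standard peaks without a partner were narrow (median 304 bp) and weak (median fold 1.82). The share of Standard peaks with a partner went up with fold, from 23.9% in the lowest decile to 99.6% in the highest.

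**Figure D3:**
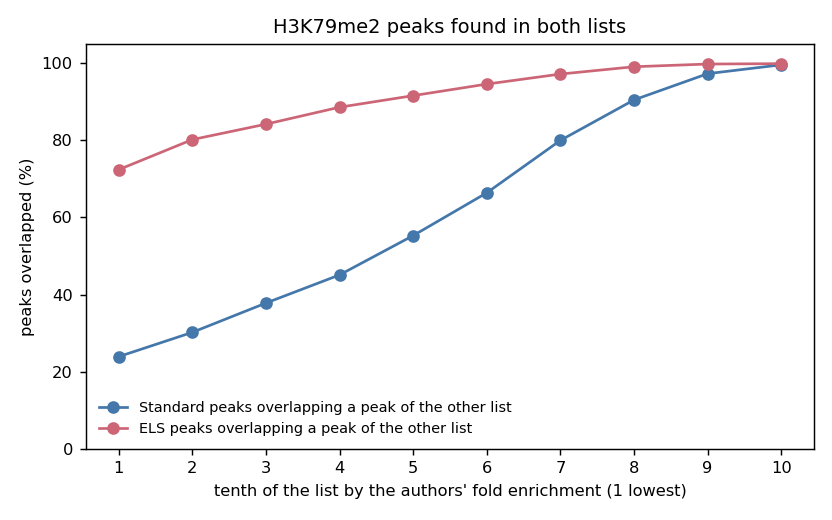
The share of peaks that overlap a peak of the other list by at least 1 bp (percent) is plotted against the decile of the list by the authors' fold, lowest first, for the Standard and the ELS list. It runs from 23.9% to 99.6% for Standard peaks and from 72.4% to 99.9% for ELS peaks.

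Covered length per gene was smaller in the ELS list across gene groups. Over 9017 genes with a peak the median log2 ratio of ELS to Standard length was -0.47. Dot1l itself, on chromosome 10, carried 18 peaks in each list, covering 22.79 kb between 80755266 and 80796138 in Standard and 17.74 kb in ELS. Its strongest peak, of fold 3.8 in Standard, lay at 80755266 to 80759768 in a promoter class. Fkbp5, the glucocorticoid-induced co-chaperone, on chromosome 17 from 28441995 to 28484252, was covered over 18.49 and 11.71 kb. Kdm2b, on chromosome 5 from 122885885 to 122896766, was covered over 5.94 and 4.88 kb, and Ppp1r1b, on chromosome 11 from 98348917 to 98352440, over 1.57 and 0.24 kb. Drd1, Drd2, Adora2a, Penk, Tac1, Pdyn, Fos, Fosb, Egr1, Bdnf and Crh had 0 peaks in both lists.

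Of the neuronal lists fixed before the data were examined, some carried the mark in most members and others in few or none. All 15 shared medium spiny neuron markers carried a peak in the Standard list, 608.1 kb in sum, against 14 and 412.8 kb in the ELS list. Postsynaptic scaffold genes went from 1239.6 to 811.9 kb, glutamate receptors from 961.0 to 606.4 kb, presynaptic release genes from 733.2 to 447.9 kb, and the Dot1l complex, with 16 of 17 members marked in each list, from 444.8 to 331.4 kb. Dlg2, named after its value was seen, went from 371.66 to 206.52 kb and Auts2 from 410.28 to 308.42 kb. Several marker lists had few members with a peak: 2 of 10 D1-type, 2 of 10 D2-type, 2 of 12 excitatory neuron, 2 of 12 astrocyte and 2 of 15 myelin genes had a Standard peak, and cholinergic interneuron, GABAergic interneuron, endothelial, meningeal and interferon lists had 0 in both lists.

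**Figure D4:**
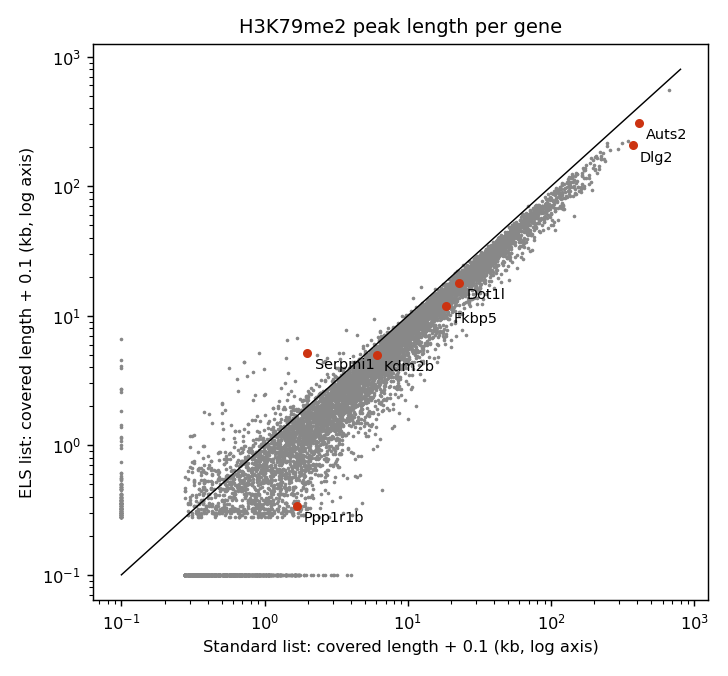
Each grey point is a gene, with the length covered by its Standard peaks on the x axis and by its ELS peaks on the y axis, both in kb plus 0.1 on log axes. Red points name genes, and points under the black line of equality have less covered length in ELS: Dot1l lies at 22.79 and 17.74 kb.

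Peaks of high fold with no partner in the other list were as follows. In the Standard list they lay at the start of Mettl21a on chromosome 1 (64616091 to 64616418, fold 3.63, and 64614970 to 64615358, fold 3.1) and in Chn1 on chromosome 2 (73612419 to 73613280, fold 3.37, and 73659519 to 73660342, fold 3.34). In the ELS list they lay in the bodies of Ccny on chromosome 18 (9425721 to 9425946, fold 2.64), Ncoa7 on chromosome 10 (30777205 to 30777434, fold 2.57), St3gal4 on chromosome 9 (35091082 to 35091269, fold 2.46), Grm5 on chromosome 7 (87995684 to 87995865, fold 2.41) and Bre on chromosome 5 (31776541 to 31776832, fold 2.36). All ELS ones were under 300 bp wide.

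Peaks went with expression. Of the 12472 protein-coding genes tested in RNA, 27.6% of the lowest 20% by expression carried a Standard peak and 88.3% of the highest 20%. In the ELS list these shares were 22.8% and 85.8%. A relation between the change in RNA and the change in peaks was not seen, but these values cannot exclude one. With edgeR 1644 genes lay at an unadjusted p under 0.05 for ELS, where other splits of the libraries gave a median of 1521. The peak lists have no replicates, so the error of their change is not known. The 100 tested genes with peaks in the ELS list only had a median log2 change in ELS of -0.03 (camera adjusted p = 0.424), and the 671 with peaks in the Standard list only had -0.03 (adjusted p = 0.424). Genes with peaks in both lists had -0.06. Camera gave an upward direction for both sets although their medians lie below 0. Over 4240 genes with at least 5 kb covered, the change in covered length and the change in RNA had r of -0.002 and rho of -0.01 across genes, which are not independent replicates.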

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

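The tests weighed in this part, the other splits of the libraries included, were chosen after the results were seen, except that the estimated correlation and DESeq2 were alternatives fixed earlier.

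Gene lists called against Standard GFP form the pattern with the most to follow up: 18 calls, 4 for early life stress (ELS) and 14 for the Dot1l overexpression vector, with astrocyte, myelin, synaptic and neuropeptide genes lower. Shallow libraries, the library of each group that dominates most genes, and Standard GFP replicate 6 are each argued against as the whole cause, since 17, 16 and 16 of the 18 lists stayed past the threshold without them, although the medians of 2, 4 and 9 of the lists turned or shrank by over 1.5 times. For the postsynaptic and presynaptic lists of overexpression replicate 6 may be the cause: 0 of these 2 lists stayed without it (medians -0.20 to 0.00 and -0.05 to 0.07), and it may add to the other 7, which are for overexpression the GABA (-0.22 to -0.03), glutamate (-0.19 to -0.07), potassium channel (-0.15 to -0.055), neuropeptide (-0.42 to -0.21), precursor (-0.24 to -0.13) and interferon lists (-0.20 to -0.12) and for ELS the astrocyte list (-0.57 to -0.37). These fits left out 1 source at a time, and the fit without dominating libraries keeps replicate 6, so joint effects were not tested. Other splits of the libraries passed a median of 5 lists for ELS and 8 for overexpression at the same threshold. Staying past it is therefore weak evidence. Genes of a list varying together may be enough, since 0 of the 18 calls held with an estimated correlation. Over the number of lists chance cannot be excluded: 72 of 100 splits of the libraries gave as many lists for ELS (4, highest other 13), 9 of 100 for overexpression (14, highest other 16) and 80 of 100 for knockdown (2, highest other 9). The 20 single calls were also weighed after the counts were seen. Only the real split reached the p of the astrocyte list for ELS (1 of 100) and of the neuropeptide list for overexpression (1 of 100). For ELS it was 30 of 100 for the shared neuronal, 25 for the ribosomal and 9 for the myelin list. Other overexpression lists ran from 4 (GABA) to 52 (glucocorticoid-induced), with presynaptic at 46, shared neuronal at 45 and interferon at 37. For knockdown it was 12 (interferon) and 7 (ribosomal). Chance cannot be excluded for any of the 20 calls. A value of 1 of 100 is the lowest that 100 splits can give. The 20 calls were also picked for their small p in the same data, among 34 lists in each main contrast. An effect of ELS on astrocyte genes stays open, as do unlabelled differences in dissection.

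Many genes stand at 0 counts in all 32 libraries, among them Gfap, P2ry12, Rpl13, Ppp2ca and Hif1a, 21567 of 52636 in all. Too little RNA is argued against for the ribosomal protein genes, of which 6 of 82 stand at 0 while the median member has 2713 counts in sum. The 6 are Rpl13, Rpl24, Rpl35, Rpl35a, Rpl32l and Rps4l. The argument assumes abundant RNA of each member, which was not tested for Rpl32l and Rps4l. A candidate explanation for part of them is that reads in overlapping genes were left out of the counts: of protein-coding genes wholly inside other gene spans 69.9% stand at 0 (95% interval 66.7 to 73.0), against 14.6% (12.3 to 17.2) of genes of like length outside any. Of the 2340 protein-coding genes at 0, 570 lie wholly inside other spans and 1479 overlap none. Spans were those of RefSeq genes, while counts are per Ensembl gene. Overlap with Ensembl genes absent from RefSeq was not tested, so the explanation is neither shown nor excluded for these 1479. Genes that share only part of their span stand at 0 in 3.9%, against 11.8% of all genes without overlap. Gfap, with 0% of its span in other RefSeq genes, Ppp2ca, with 2.2%, and Rpl13, with 4%, are not covered by RefSeq overlap. No biological explanation was tested. A 0 for such a gene therefore says nothing of its expression here.

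The H3K79me2 list of ELS covers less length than the Standard list, 0.735 of it. A loss confined to particular genes is argued against, since 98.8% of the 4521 genes with at least 5 kb covered have less covered length in ELS. Lower sensitivity of the ELS list is a candidate explanation: 99.6% of Standard peaks in the highest decile by fold have an ELS partner and 23.9% in the lowest. Lower H3K79me2 in the ELS animals cannot be told apart from it, because there is 1 list per group and the depth of the ChIP libraries is not given in the sources used here.

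With 0 genes past the threshold in the real grouping with edgeR, all 100 of 100 splits give as many in each of the 5 contrasts by construction, which tests nothing. The highest other split gave 2 for ELS, 8 for overexpression, 0 for knockdown, 11 for knockdown against Standard GFP and 1 for overexpression against ELS GFP. At an unadjusted p under 0.05 chance cannot be excluded for any contrast: 22 of 100 splits gave as many genes as ELS (1644, highest other 2065), 76 as overexpression (1524, highest other 2224) and 45 as knockdown (866, highest other 1664). For knockdown against Standard GFP it was 40 of 100 (1515, highest other 2357) and for overexpression against ELS GFP 91 of 100 (936, highest other 1780). DESeq2 called 85, 41, 2, 74 and 2 genes in the same order of contrasts. The splits were run with edgeR only, so how many genes DESeq2 calls in other splits was not tested.

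For the correlations, 5 of 100 regroupings lay as far from the regrouped mean as the ELS and overexpression value (0.703, highest other 0.715), 96 as ELS and knockdown (-0.458, highest other -0.087) and 46 as overexpression and knockdown (-0.068, highest other 0.206). For RNA at genes with peaks in the ELS list only, 40 of 100 splits gave a camera p as small (p = 0.332, smallest other 0.00181), and 51 for the Standard list only (p = 0.424, smallest other 0.051). Chance cannot be excluded for any of these.

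A library was singled out when it lay far from the other 7 of its group by Dixon's test, which by chance happens in about 1 in 20 groups. This held in 72 of 292 groups of named genes, where 15 would be expected, and in 4 of 24 groups of library measures. The genes were named because of their differences, so they are not a fair sample. Among library measures, overexpression replicate 3 had the most genes detected of its group (24881). Knockdown replicate 7 had the lowest share of counts in the 10 most abundant genes (38.2%). Overexpression replicate 4 had the highest mitochondrial share (9.51%). Standard GFP replicate 5 had the lowest Dot1l level (10.6 CPM, from 6 counts). Values below are CPM, highest of the group unless said otherwise.

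ELS GFP replicate 2 stood apart at 16 genes: Timm17a 405, Heyl 121, Dusp5 149, Acsl5 62, Gm47962 67.2, Drd2 630, Penk 259, Osgepl1 44.6, Bdh1 177, Rrs1 94.3, Enpp1 349, Stard4 342, Pde1b 141, Rpl10a 24.5 and Isg15 227, and lowest at Gm9774 with 0. ELS GFP replicate 6 was lowest at Gja1 with 12.5.

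Standard GFP replicate 6 stood apart at 14 genes: Rfc5 223, Gm9774 119, Nkd1 110, Ddr1 140, Neu4 116, Crhr1 157, Grin3a 132, Gabra4 175, Dlg1 528, Dlgap4 399, Nlgn2 397, Syt1 2180, Oas1a 263 and Gbp7 232. Standard GFP replicate 1 was highest at Ptrhd1 142, Zfp949 348, Plin4 166 and Pclo 991, and replicate 2 at 4933413J09Rik 0.237, a gene at 0 in the other 7. Standard GFP replicate 5 was highest at Oprd1 33.5 and lowest at Dot1l 10.6, Rpl10a 0, Aspa 0 and Sema5a 1.76. Replicate 4 was lowest at Cspg4 0 and Rps12 0, and replicate 7 at Cdkn1a 0. Replicates 5 and 4 held only 0.546 and 0.314 M counts, so their low values rest on few or no counts and may be sampling at low depth.

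Overexpression replicate 1 stood apart at 10 genes, among them Gm11361 32.6, Gm29478 120, Egr1 155, Hepacam 499, Tmem70 193, Nlgn2 225, Sema6a 271 and Rpl32 219, and lowest at Kdm2b with 10.3. Overexpression replicate 8 was highest at the neuronal genes Drd1 39.3, Pde1b 172 and Foxp1 324. Overexpression replicate 2 was highest at Ildr1 86.8 and Ephb3 43.6, replicate 3 at Tarsl2 11.7, replicate 4 at Fkbp5 122 and replicate 7 at Usp18 16.9. Replicate 4 was lowest at Gabra2 with 34.2 and replicate 5 at Vamp1 with 1.1. Knockdown replicate 7 was highest at Pgam2 278, Lipc 479, H2afx 425 and Fam189a2 190. Knockdown replicate 3 was lowest at Adora2a with 1.04, and replicate 6 at Bdnf with 0 and Rpl17 with 10.1.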

How the results depend on the processing

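Fits without shallow libraries, dominating libraries, Standard GFP replicate 6 or the 10 most abundant genes, and list tests with quality weights, were chosen after the results were seen. No paired analysis was possible because the peak lists are 1 per group, no ChIP value per library was used, and the letters and numbers of RNA titles recur within groups, so they pair no single libraries; both were fitted as factors. Of the values of the leading results under alternatives, 28 moved and all others kept their call. Of 2151 values of 167 named gene results, 2028 kept direction and side of the threshold, 26 newly passed it (20 with DESeq2, 6 without shallow libraries) and 97 reversed, in 37 results. With 4-fold changes the self-test called 60 to 70 genes of each set and with 2-fold changes 13 to 18, so depth and spread limit calls of small changes. The no-filter setting shifts the median log2 fold change by 0.087 for ELS and 0.162 for overexpression. Where no reason is given, the cause was not tested.

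Counts of genes past the threshold were 0 with edgeR. DESeq2 gave 85 for ELS, 41 for overexpression, 2 for knockdown, 74 for knockdown against Standard GFP and 2 for overexpression against ELS GFP. An adjusted p under 0.10, a looser threshold by construction, gave 41 for knockdown against Standard GFP. Leaving out shallow libraries gave 7 for ELS and 18 for overexpression. Over all alternatives the smallest adjusted p ran from 0.000896 to 0.96 for ELS, 0.00995 to 0.823 for overexpression and 0.000887 to 0.936 for knockdown.

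Gene lists past the threshold were 4 for ELS, 14 for overexpression and 2 for knockdown. An estimated correlation gave 0, 0 and 0, and fry 0, 0 and 0. Both let the genes of a list vary together, but whether this alone ended the calls with fry was not tested. Quality weights gave 7 for ELS, 7 for overexpression and 4 for knockdown. For knockdown the title number as a factor gave 0, leaving out shallow libraries 4 and leaving out dominating libraries 4. Leaving out Standard GFP replicate 6 gave 4, although that library is in neither group of the knockdown contrast. Of the 14 overexpression calls, quality weights lost 8, among them presynaptic (adjusted p = 0.254), glucocorticoid-induced (adjusted p = 0.172) and postsynaptic genes (adjusted p = 0.0779). The title number lost axon guidance and interferon-stimulated genes (adjusted p = 0.0507 each), and leaving out replicate 6 lost postsynaptic and presynaptic genes (adjusted p = 0.258 each). Potassium channel genes were lost without shallow libraries (adjusted p = 0.0781), and mitochondrial mRNAs (adjusted p = 0.314) and interferon-stimulated genes (adjusted p = 0.0583) without dominating libraries. No library other than Standard GFP replicate 6 was left out alone. The ELS and knockdown correlation moved to -0.144 with the title number as a factor.

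Standard peaks overlapped were 36.1% with a reciprocal overlap, 57.1% with a fold at or over the median and 60.8% merged, against 62.6%. ELS peaks overlapped were 40%, 91.9% and 86.2%, against 90.8%. The reciprocal values are lower by construction.

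Reversed log2 fold changes follow. With DESeq2 size factors in the edgeR fit, Ppp1r1b for knockdown was -0.03. With no filter, Egr1 for ELS was 0.00 and Fos for overexpression 0.02. With only 2 groups, Ppp1r1b for knockdown was -0.02. Without the 10 most abundant genes it was -0.01. With DESeq2, knockdown gave H2afx -0.48, Penk -0.01, Ppp1r1b -0.02 and Isg15 0.39, and overexpression Plin4 0.12 and Crhr1 0.27.

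With voom quality weights, ELS gave Dot1l -0.04, Kdm2b 0.09, Drd2 -0.90, Fos 0.17, Fosb 0.02, Egr1 0.12, Bdnf 0.29 and Rpl22 0.04. Overexpression gave Dot1l -0.01, Kdm2b 0.14, Ppp1r1b -0.56, Fos 0.32, Fosb 0.34, Crhr1 0.18, Rpl18 0.04 and Oas1a 0.28. Knockdown gave H2afx -0.13, Kdm2b 0.15, Drd2 0.33, Adora2a 0.17, Tac1 -0.26, Ppp1r1b -0.18, Bdnf -0.06, Fkbp5 0.19 and Isg15 0.21.

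With the title number, Kdm2b for ELS was 0.01, Egr1 for ELS 0.09 and Ppp1r1b for knockdown -0.06. With the title letter, ELS gave Kdm2b 0.19, Drd2 -0.69 and Fos 0.36. Knockdown gave Kdm2b 0.01, Ppp1r1b -0.71, Egr1 0.07 and Isg15 0.36, and overexpression against ELS GFP Stard4 0.14. With surrogate variables, ELS gave Dot1l -0.11, Kdm2b 0.39, Fos 0.51, Fosb 0.27, Egr1 0.40 and Fkbp5 0.16. Overexpression gave Kdm2b 0.23, Fos 0.39, Fosb 0.48, Bdnf -0.23, Crhr1 0.38, Oas1a 0.35 and Gbp7 0.01. Knockdown gave Penk -0.49, Tac1 -0.01 and Ppp1r1b -0.70.

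Without Standard GFP replicate 6, ELS gave Kdm2b 0.46, Fos 0.14 and Egr1 0.06. Overexpression gave Kdm2b 0.28, Fos 0.17, Crhr1 0.37, Dlgap4 0.02, Nlgn2 0.05 and Oas1a 0.66; that library held most Crhr1 and Oas1a.

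Without shallow libraries, ELS gave Dot1l -0.05, Fos 0.05, Egr1 0.13 and Rpl22 0.26. Overexpression gave Ppp1r1b -0.10, Fos 0.07, Egr1 0.02 and Plin4 1.34, and knockdown H2afx -0.43 and Ppp1r1b -0.03; the library that held most H2afx and the one that held most Plin4 are among those left out. Without dominating libraries, ELS gave Dot1l -0.06, Drd2 -0.83, Fos 0.12 and Egr1 0.02. Overexpression gave Fos 0.27, Bdnf -0.14, Kcnj3 -0.02 and Sema6a -0.04. Knockdown gave Kdm2b 0.03, Drd2 0.61, Adora2a 0.03, Tac1 -0.17, Egr1 0.08 and Isg15 0.40, and overexpression against ELS GFP Stard4 0.05; ELS GFP replicate 2, which held most Drd2, Isg15 and Stard4, is left out there.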

Other observations

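Gene groups not described above were lower or higher without passing their test on all 32 libraries. Of 37 other histone lysine methyltransferases and demethylases 25 were lower in ELS (camera adjusted p = 0.186). For knockdown 21 were higher, at a median log2 of 0.03 (adjusted p = 0.13), and the list passed without the shallow (adjusted p = 0.0464) and without the dominating libraries (adjusted p = 0.0222), but not with an estimated correlation (adjusted p = 0.998) and at a median of -0.015 with surrogate variables. Of the list's 45 members 37, not chosen by RNA, had a peak in each list, over 911.5 kb of Standard and 713.4 kb of ELS peaks. All 20 postsynaptic scaffold genes were lower with knockdown against ELS GFP, at a median log2 of -0.17 (adjusted p = 0.0693). GABA genes were lower in 13 of 19 for ELS (adjusted p = 0.0511; adjusted p = 0.331 without Standard GFP replicate 6; adjusted p = 0.206 with quality weights), and 3 of them passed when adjusted over the list alone. The list passed with the title number as a factor (adjusted p = 0.0497), without the shallow libraries (adjusted p = 0.0296) and without the dominating libraries (adjusted p = 0.0244). With an estimated correlation it did not pass on all libraries (adjusted p = 0.553), without the shallow (adjusted p = 0.603) or without the dominating ones (adjusted p = 0.32), and with surrogate variables its median turned from -0.09 to 0.02. Nuclear respiratory chain genes carried 245.7 kb of Standard and 207.4 kb of ELS peaks, and circadian clock genes 216.6 and 172.4 kb.

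Some genes had more covered length in the ELS list. Serpini1, which encodes neuroserpin, went from 1.89 to 5.06 kb, Lsm7 from 1.58 to 6.66 kb, Erh from 3.57 to 7.67 kb and Recql from 0.82 to 5.08 kb. Among those with less, Ift46 went from 6.49 to 0.35 kb, Celf2 from 341.5 to 221.64 kb and Foxp1 from 237.89 to 155.91 kb. All were chosen after their values were seen. A wide peak near several genes counts in full for each, so a split or joined peak can move these lengths. Recql had 1 peak in each list, with a fold of 3.68 in Standard and 3.03 in ELS. Whether such peak borders explain these genes was not tested.

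Chromosome X held 110 Standard and 15 ELS peaks, a ratio of 0.136, while the ratio over the 19 autosomes ran from 0.845 to 0.945. These X peaks were 0.09% and 0.01% of their lists, where no autosome held fewer than 3000 and 2775. Their median folds were 1.79 and 1.69, against 1.96 and 1.92 over all peaks. A loss particular to X cannot be told apart from lower sensitivity for weak peaks. Among the genes with a peak, 510 stood at 0 counts in all RNA libraries. Over 50% of the higher group's CPM lay in 1 library for 43.2% of the ELS genes at an unadjusted p under 0.05 and for 6.9% of the rest. For overexpression these shares were 44.8% and 7.5%, and for knockdown 36.5% and 3.5%. Correlations within groups ran from 0.737 (Standard GFP replicates 4 and 5) to 0.962 (knockdown replicates 1 and 8).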
